A study of Mus musculus with 4 samples.

How the data were processed

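The series holds 4 RNA-seq libraries, which the labels describe as S1PR1-positive endothelial cells of mouse lung, sorted as reporter-positive, CD31-positive and CD45-negative. Per the labels' protocols the lungs were made into single-cell suspensions, RNA was extracted with Trizol and checked on a Bioanalyzer, and libraries were made from oligo-dT-selected RNA. The deposited table holds raw counts of reads per gene, whole numbers with 1 column per sample, which the authors made with STAR and featureCounts on the mouse genome build mm10, per the submitters' processing notes. Versions, settings, the annotation, strand handling and the treatment of reads that map to several genes are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense pairs are uncertain. The labels do not say whether a library came from 1 animal or several.

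Each column was matched to its sample by its name. The groups follow the treatment label, with 1 library for no LPS and 1 each for 8, 16 and 20 h of LPS at 10 mg/kg. The treatment protocol lists times of challenge, which can be read as times since a single injection or as times of injection, and the label hours are used as times only. A further time point named in the protocol is not analysed here. The table had 39056 genes, of which 17267 had 0 reads in all 4 libraries. Gene symbols came from the GENCODE M21 annotation of the same build by stable gene identifier: 38872 identifiers (99.5%) matched, and 34299 matched with their version number. Coordinates are those of this annotation, counted from 1, and all genes given with coordinates are annotated as protein coding.

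Totals were 28060685, 28905776, 27843147 and 27566454 reads in the libraries labelled no LPS, 8 h, 16 h and 20 h. A level of 3 reads, the upper limit that 0 reads allows, was 0.106, 0.104, 0.108 and 0.108 CPM on the scaled totals. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

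Counts were scaled with edgeR's TMM factors from all 4 libraries, and CPM values are on this scale. With 1 library per group no test of a pair of libraries is possible, and each of the 5 pairs was described by a rule of size. The interval of each fold is the exact conditional binomial (Clopper-Pearson) 95% interval for 2 counts, converted with the scaled library sizes. A gene was called higher or lower with a fold of at least 2, an interval excluding 1 and at least 1 CPM in the higher library. Log2 ratios used a prior count of 2. These calls compare libraries, not conditions. For each of 46 gene lists, the members called, the median log2 ratio of measured members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, were computed with a fixed seed of 1, and the percentile is a description of these libraries. Where explanations were weighed, a list counted as high above percentile 97.5. The lists covered S1P signalling, endothelial identity and its subtypes, junctions, inflammation, immediate-early factors, the cell cycle, growth factors, coagulation, antigen presentation, metabolism, stress responses, RNA quality, sex-linked transcripts (of 6 listed, Xist alone was measured, with no call against no LPS) and 14 sets of markers of other cells. The linear trend over 0, 8, 16 and 20 h was tested in edgeR with glmQLFit and glmQLFTest, 2 residual degrees of freedom, genes of at least 1 CPM in at least 1 library and Benjamini-Hochberg adjustment.

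Named genes were, in each comparison with no LPS, the 8 highest and the 8 lowest called genes by log2 ratio with at least 100 reads in the higher library, and the 5 highest and 5 lowest between successive times. In the trend they were the 5 with the smallest p in each direction, and in each list up to 4 measured members with the largest absolute log2 ratio, or all members of lists of 6 or fewer. S1pr1, Egr1, Stat3, Sphk1, Spns2, Klf2, Pecam1, Cdh5 and Ptprc were always included, and model gene names, clone names and pseudogenes were skipped in rankings. Some genes that the rule selects are not reported here. Kdr, Tek, Erg, Emcn, Epcam, Sftpc, Prrx1, Vim and the other genes of the marker plot, the genes behind the opposite calls and the genes named under other observations were chosen after their values were seen. The groups, the 46 lists, the rule for named genes, the rule of size, the trend test and the alternatives were fixed before the data were examined. A correction for transcript GC content, the lists of mesenchymal and amino acid genes, the chi-square between pairs of libraries, the trend simulation at the estimated variation and the tests named as such under other observations were added later.

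The alternatives were scaling by library size, by DESeq2 size factors and by upper quartiles, prior counts of 0.5 and 10, no count filter or a minimum of 10 CPM, a fold threshold of 4, a stricter interval level of 99.9%, libraries thinned to the smallest total, and the removal of 280 marker, mitochondrial and ribosomal genes. For the trend they were DESeq2, its size factors, no filter, the order of the times, log2 of the hour plus 1, and each library left out in turn. Scaling moved the median log2 ratio of all measured genes by at most 0.03.

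The procedure was tested on simulated counts drawn from these libraries' means and totals. For the pairs of libraries these counts had counting error alone, for which the interval is built, so the false calls below leave out biological variation. With a simulated biological coefficient of variation of 0.2, unchanged libraries gave 291 calls per comparison on average. In the 8 h comparison with no LPS, 100 of 100 genes changed 3-fold and 100 of 100 changed 6-fold were called, with 13 false calls over 39056 genes, and 95.4% of intervals covered the true fold. In the 20 h comparison 99 of 100 were called at 3-fold, with 12 false calls, and between 8 h and 16 h there were 10 false calls. For the trend, with a simulated biological coefficient of variation of 0.1, 91 of 100 genes at 2-fold by the last hour and 100 of 100 at 4-fold passed, with 5 false calls over 10784 genes. The fit of these libraries estimated 0.247, and at that value 8 of 100 and 73 of 100 passed, with 1 false call. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.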

Results

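Polyadenylated RNA was measured by sequencing in 4 libraries labelled as mouse lung cells, 1 library for each of 4 labels: no LPS, and 8, 16 and 20 h of LPS. Lipopolysaccharide (LPS, endotoxin) is an outer-membrane component of Gram-negative bacteria that activates Toll-like receptor 4 and injures the lung endothelium, and the labelled dose was 10 mg/kg into the peritoneum. The labels describe endothelial cells sorted by flow cytometry from reporter mice that mark cells expressing the sphingosine-1-phosphate (S1P) receptor S1PR1 with green fluorescent protein. The gate took cells positive for the reporter and the endothelial surface protein CD31 and negative for the leukocyte protein CD45. The title of the series places the samples in a study of how S1PR1-positive endothelial cells take part in the repair of the lung vessel wall.

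The libraries were deep and even. The count totals were 28060685 reads in the library labelled no LPS, 28905776 at 8 h, 27843147 at 16 h and 27566454 at 20 h, a ratio of 1.05 between the largest and the smallest. Between 11316 and 11430 genes reached 1 CPM (reads scaled to a common library total) in a library, and 11803 genes reached it in at least 1 library and are called measured genes here. A gene with no reads could have had a level of up to 0.108 CPM in the library with the smallest total (3 reads). Mitochondrially encoded transcripts took 1.80% of reads with no LPS, 1.36% at 8 h, 1.40% at 16 h and 1.90% at 20 h. With 1 library per label there was no replicate check of any difference between labels. The intervals below cover counting error only, and "higher" and "lower" stand for a rule of size, not for a test: a scaled fold of at least 2, a 95% interval of the fold that excludes 1, and at least 1 CPM in the higher library.

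The first question for these libraries was whether they held the cells that the labels name. Transcripts that define endothelial cells were close to absent in all 4 libraries. Pecam1, which encodes CD31 (chromosome 11, 106654217 to 106750628, minus strand, mm10), had 7 reads in the library labelled no LPS, 2 at 8 h, 2 at 16 h and 1 at 20 h. Cdh5, which encodes the junction protein VE-cadherin, had 5, 6, 6 and 9 reads in the same order, and Kdr, which encodes the main receptor for VEGF, had 8, 12, 9 and 3. Erg and Emcn had 0 reads in all 4 libraries, and Tek had 0, 0, 0 and 2. Of 28 pan-endothelial genes, 19 lay below 1 CPM in the library labelled no LPS, and the median of the list there was 0.212 CPM. S1pr1 itself (chromosome 3, 115710433 to 115715072, minus strand), the gene behind the sort, had 27 reads with no LPS, 87 at 8 h, 79 at 16 h and 29 at 20 h. The medians of the other endothelial lists in the library labelled no LPS were 0.354 CPM for general capillary, 0.283 for aerocyte, 0.0708 for arterial, 0.814 for venous and 0 for lymphatic genes.

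List medians of the other cell types of the lung were low as well. The leukocyte list had the highest median of the 14 marker lists in the library labelled no LPS, at 0.991 CPM. Ptprc, which encodes CD45, had 42, 37, 31 and 38 reads in the libraries labelled no LPS, 8 h, 16 h and 20 h. The lung epithelial genes Epcam and Sftpc had at most 3 and 1 reads. No member of the T cell, NK cell or erythroid lists was measured, and 1 B cell gene, 2 platelet genes, 2 alveolar type 2 genes, 2 smooth muscle genes and 3 mesothelial genes were. The leukocyte list had 8 of 12 measured, the macrophage list 8 of 20 and the fibroblast list 7 of 16. In the fibroblast list 5 genes reached 10 CPM in at least 1 library, and in the macrophage list 3. Single genes of some lists were well expressed, among them Cd68 at 99.7 CPM, the collagen gene Col3a1 at 168 CPM and the transcription factor gene Etv5 at 98.7 CPM with no LPS. Another collagen gene, Col1a1, had 2, 3, 4 and 0 reads with no LPS and at 8, 16 and 20 h. The intermediate filament gene Vim stood at 2358 CPM with no LPS, 2760 at 8 h, 2871 at 16 h and 2543 at 20 h. Prrx1, a homeobox gene of mesenchymal cells, stood at 210, 209, 213 and 211 CPM. The identity genes thus went against the labels, so each time given below, such as "at 8 h", stands for the column with that label, and every direction is a direction between these columns.

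**Figure D1:**
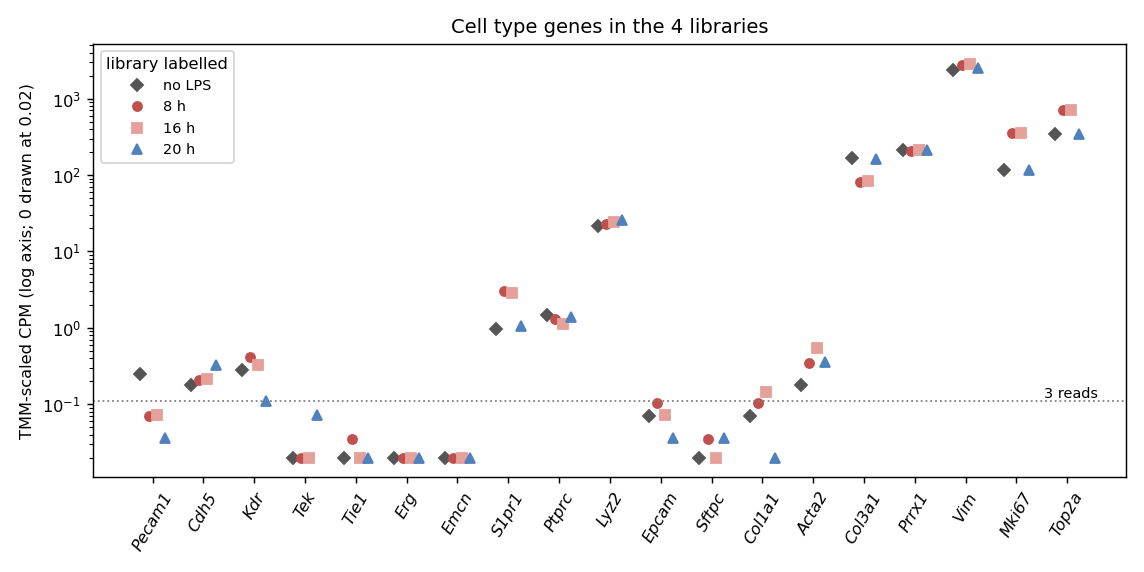
TMM-scaled CPM (log axis, 0 drawn at 0.02) of 19 cell type genes in the libraries labelled no LPS, 8 h, 16 h and 20 h, 1 point per gene and library, with a dotted line at the level of 3 reads. Pecam1 lies between 0.0361 and 0.248 CPM and Erg and Emcn at 0, while Vim lies between 2358 and 2871 CPM.

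The earliest label was addressed by setting the library labelled 8 h against that labelled no LPS. At 8 h, 494 genes were higher and 487 were lower. Mitotic genes, growth factor genes and immediate-early genes were among the higher ones, and sterol synthesis genes and several acute phase genes were among the lower ones. S1pr1 was 3.17-fold higher (95% counting interval 2.04 to 5.08), at 3.03 CPM against 0.955 CPM. The S1P exporter gene Spns2 (chromosome 11, 72451638 to 72489904, minus strand) was 7.31-fold higher (5.13 to 10.7), and Sphk1, which encodes a kinase that makes S1P (chromosome 11, 116530925 to 116536674, plus strand), was 4.22-fold higher, at 6.27 CPM against 1.49 CPM. Egr1, an immediate-early transcription factor gene (chromosome 18, 34859823 to 34864984, plus strand), was 6.35-fold higher (5.57 to 7.27), and Klf2, which encodes a shear-responsive factor in endothelium, was 3.05-fold higher (2.48 to 3.76). Stat3 was not called, at 1.39-fold (1.30 to 1.48). S1pr1, Sphk1, Spns2, Egr1, Klf2 and Stat3 had been named in advance from the subject of the study. Pecam1, Cdh5 and Ptprc were not called: Pecam1 was at 3.56-fold lower (0.677 to 35.1), Ptprc at 1.15-fold lower (0.723 to 1.84) and Cdh5 at 1.18-fold higher on 6 against 5 reads.

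Ratios were ranked among called genes with at least 100 reads in the higher library. Among the genes with the largest ratios, the higher side held Tinagl1, which encodes a secreted matrix protein, at 7.24-fold (6.10 to 8.64), the adhesion receptor gene Adgrg1 at 7.69-fold, the oxysterol hydroxylase gene Cyp39a1 at 7.29-fold, Fam171a2 at 7.31-fold, the actin-bundling gene Pls1 at 7.09-fold and the lymphoid transcription factor gene Ikzf2 at 6.34-fold. The lower side was led by Tspoap1 at 16.7-fold (15.1 to 18.5), followed by the noncoding Platr26 at 14.4-fold, the cytokine gene Il17f at 13.4-fold, Nlrp12 at 12.7-fold, Rsph10b at 10.6-fold, Dcdc2b at 10.4-fold and Otog at 9.59-fold. Lcn2, an acute phase gene whose product binds bacterial iron carriers (chromosome 2, 32384633 to 32388252, minus strand), was 10.1-fold lower (9.31 to 10.9), at 24.8 CPM against 250 CPM.

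Of the 30 measured G2/M mitotic genes, 17 were higher, none was lower and 13 were not called, and the list's median log2 ratio of 1.06 stood at percentile 100 of random lists matched on expression. The mitotic spindle gene Nusap1 was 3.50-fold higher (3.06 to 4.02), the proliferation marker gene Mki67 3.08-fold (2.96 to 3.21), the cyclin gene Ccnb2 2.85-fold and Prc1 2.84-fold. Among 25 measured G1/S replication genes 3 were higher and 22 not called, with a median of 0.45 (percentile 100); they were the thymidine kinase gene Tk1 at 4.62-fold (4.12 to 5.20), E2f2 at 3.17-fold and the ribonucleotide reductase gene Rrm2 at 2.46-fold. Of 23 measured angiogenesis and growth factor genes 7 were higher, 2 lower and 14 not called (median 0.37); Id3 was 4.35-fold higher (3.59 to 5.29), Vegfc 3.61-fold, the peptide ligand gene Apln 3.38-fold and the VEGF co-receptor gene Nrp1 2.80-fold. The Hippo-YAP and TGF-beta list had 5 of 20 measured members higher and 15 not called (median 0.34), with Ankrd1 at 5.78-fold (4.60 to 7.34), Ccn2 at 5.88-fold and Tgfb1 at 3.50-fold. In the coagulation and fibrinolysis list 3 of 16 were higher and 13 not called (median 0.48), among them the tissue plasminogen activator gene Plat at 3.10-fold (2.55 to 3.79) and the protease receptor gene F2rl1 at 3.08-fold. The immediate-early list had 4 of 26 higher and 22 not called (median 0.35), with Klf10 at 2.61-fold and Ier3 at 2.35-fold beside Egr1 and Klf2.

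The lists of inflammation went in mixed directions at 8 h. Of 17 measured adhesion and activation genes, 2 were higher, 1 was lower and 14 were not called (median 0.29, percentile 98.5): the selectin genes Sele, 2.63-fold (2.25 to 3.09), and Selp, 2.23-fold, were higher, and Cd40 was 2.65-fold lower. Of 11 measured chemokine and cytokine genes, 3 were higher, 2 lower and 6 not called (median 0.41); Ccl20 was 3.84-fold higher (1.88 to 8.62) and the neutrophil attractant gene Cxcl1 2.17-fold higher, while the alarmin gene Il33 was 4.32-fold lower (4.12 to 4.54) and Cxcl2 3.23-fold lower. The NF-kB list had 1 of 18 higher, its feedback gene Tnfaip3 at 2.21-fold (1.81 to 2.70), and 17 not called (median 0.21, percentile 96.3). Among 12 measured interferon-stimulated genes of 40 listed, 3 were higher and 9 not called (median 0.08, percentile 66.0): Ddx58, which encodes the RNA sensor RIG-I, at 3.12-fold, Ifit2 at 2.64-fold and Irf8 at 2.53-fold. STAT3 targets and acute phase genes had 1 of 18 higher, 4 lower and 13 not called (median -0.08); Timp1 was 2.34-fold higher (2.09 to 2.61), and next to Lcn2 the ceruloplasmin gene Cp was 3.04-fold and Cebpd 2.32-fold lower. The S1P list as a whole had 3 of 15 higher, 1 lower and 11 not called, with a median of -0.17 at percentile 8.22, opposite in sign to the 3 higher members; the lower member was the S1P transporter gene Mfsd2b at 4.53-fold.

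Sterol synthesis genes had the lowest median among the lists of 10 or more measured genes, -0.43 (percentile 0), with 2 of 17 lower and 15 not called; Insig1, a regulator of sterol sensing, was 3.21-fold lower (2.88 to 3.58). Mitochondrially encoded transcripts had a median of -0.60 with 1 of 7 lower, mt-Nd6 at 2.92-fold, while nuclear-encoded oxidative phosphorylation genes had a median of 0.18 with 1 of 76 lower, Cox6a2 at 2.21-fold. The junction and barrier list had 1 of 18 lower, Slit2 at 2.27-fold, and the pan-endothelial list 1 of 10 higher, Flt1 at 2.33-fold, and 1 lower, Nos3 at 2.86-fold. MHC class I genes had 1 of 15 higher, H2-T23 at 2.03-fold, and 1 lower, H2-K1 at 2.74-fold. The p53 list had 1 of 28 higher and 3 lower, among them Trp53inp1 at 2.65-fold lower. The hypoxia and redox list had 1 of 20 higher, the heme oxygenase gene Hmox1 at 2.62-fold (2.54 to 2.70), and 1 lower, Car9 at 4.01-fold. The unfolded protein response list had 1 of 22 lower, Dnajb9 at 2.15-fold, the ribosomal protein list 4 of 78 higher, and the glycolysis and heat shock lists had 0 of 21 and 0 of 10 called. Calls in the subtype lists were 2 of 6 lower for general capillary, 2 of 7 higher for aerocyte, 2 higher and 1 lower of 7 for arterial, 2 of 8 higher for venous and 1 of 2 lower for lymphatic genes, and 1 of 3 MHC class II genes was higher.

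Some markers of other cell types were called at 8 h beside these groups. The keratin genes Krt8 and Krt18, from the airway list, were 2.48-fold (2.20 to 2.81) and 2.38-fold (2.22 to 2.56) higher at 8 h, the alveolar type 1 gene Rtkn2 was 3.08-fold higher, and the macrophage gene Adgre1 was 2.54-fold higher (1.27 to 5.44) at 1.08 CPM. In the fibroblast list 3 of 7 were higher and 2 lower, with Gsn at 2.81-fold and Npnt at 2.67-fold higher and the matrix genes Dcn and Col3a1 at 3.20-fold and 2.05-fold lower. The neutrophil gene S100a8 was 5.76-fold lower (2.39 to 16.8), and 0 of 8 leukocyte genes, 0 of 3 mesothelial genes and none of the smooth muscle, B cell, platelet and alveolar type 2 genes were called. Among nuclear and degradation-sensitive RNAs 1 of 6 was lower, Snhg11 at 2.58-fold, and the median was -0.31 (percentile 1.66). The count of 981 called genes became 332 with a minimum of 10 CPM, of which 62.4% were higher, and 187 with a fold threshold of 4, of which 32.6% were higher. Genes with near-identical copies, such as Gapdh at 17.4 CPM and Rps6 at 1.24 CPM with no LPS, are uncertain, since how reads shared between copies were counted is not given in the sources used here.

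**Figure D2:**
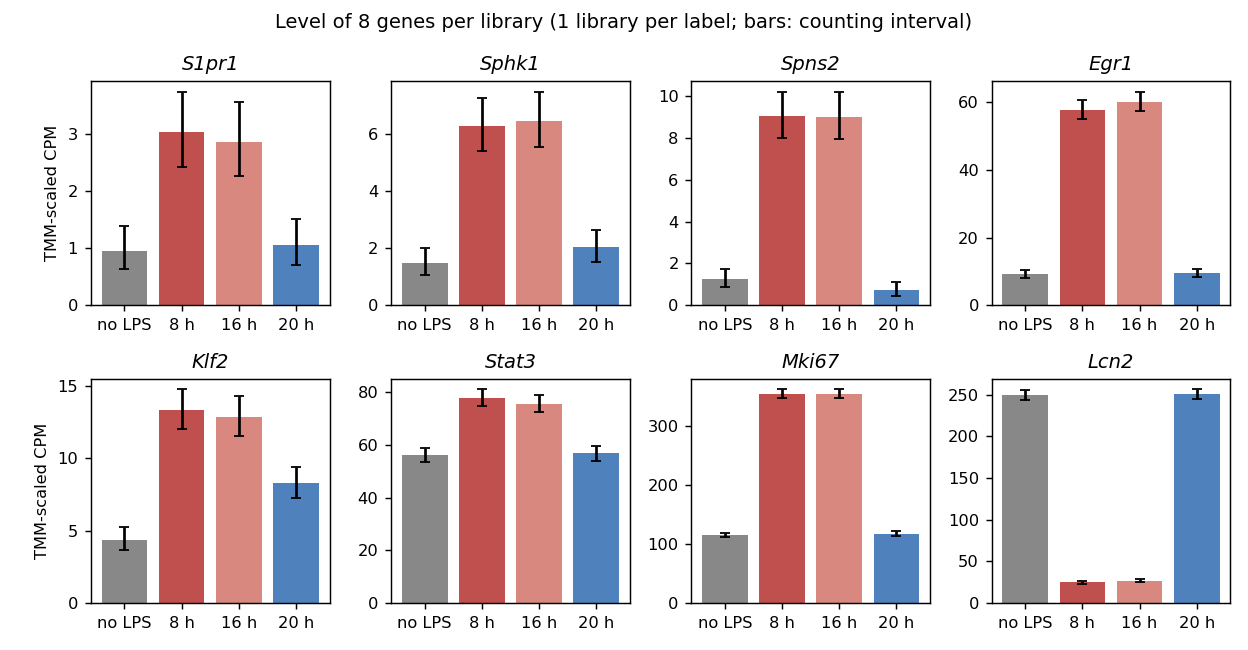
TMM-scaled CPM of 8 genes in the libraries labelled no LPS, 8 h, 16 h and 20 h, each axis starting at 0, 1 bar per library with an exact Poisson 95% counting interval. S1pr1 stands at 0.955, 3.03, 2.85 and 1.05 CPM and Lcn2 at 250, 24.8, 26.8 and 250 CPM.

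The middle label was addressed by setting the library labelled 16 h against that labelled no LPS. Here 488 genes were higher and 483 lower. S1pr1 was 2.98-fold higher (1.91 to 4.81), Spns2 7.29-fold (5.10 to 10.7), Sphk1 4.35-fold (3.09 to 6.24), Egr1 6.61-fold (5.80 to 7.57) and Klf2 2.94-fold (2.39 to 3.63). Stat3 was not called, at 1.35-fold (1.26 to 1.44), nor were Pecam1, Cdh5 and Ptprc. Among called genes with at least 100 reads in the higher library, Mmp12 had the largest ratio on the higher side. This gene, which encodes macrophage elastase (chromosome 9, 7344381 to 7369499, plus strand), was at 4.87 CPM against 0.212 CPM, with a counting interval of the fold of 10.3 to 63.6. It was followed by Pls1 at 8.98-fold, Adgrg1 at 8.35-fold, Tinagl1 at 7.60-fold, the scavenger receptor gene Cd36 at 7.48-fold (4.34 to 13.8) and Reps2 at 6.82-fold. On the lower side stood Platr26 at 23.1-fold (11.9 to 51.2), Tspoap1 at 17.8-fold (16.0 to 19.8), Nlrp12 at 12.3-fold, Dcdc2b at 12.1-fold, Aqp9 at 9.59-fold, Lcn2 at 9.32-fold (8.64 to 10.1), Otog at 8.33-fold and Sh2d6 at 8.05-fold.

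By group, 17 of 30 G2/M mitotic genes were higher and 13 not called at 16 h (median 1.07), with Nusap1 at 3.69-fold (3.23 to 4.24), Mki67 at 3.08-fold and Plk1 at 2.69-fold. Of 25 G1/S genes 4 were higher (median 0.44), with Tk1 at 4.77-fold and Rrm1 at 2.01-fold. The angiogenesis list had 8 of 23 higher and 15 not called (median 0.45), with Id3 at 4.71-fold (3.90 to 5.73) and Apln at 3.41-fold, and the Hippo-YAP and TGF-beta list 6 of 20 higher (median 0.45), with Ccn2 at 5.90-fold (4.04 to 8.87) and Tgfb1 at 3.88-fold. Coagulation genes had 3 of 16 higher (median 0.54) and immediate-early genes 4 of 26 higher (median 0.39). Adhesion genes had 3 of 17 higher and 1 lower (median 0.30), with Ackr3 at 2.03-fold joining Sele and Selp. Chemokine and cytokine genes had 3 of 11 higher and 1 lower (median 0.30), with the monocyte attractant gene Ccl2 at 2.19-fold (1.97 to 2.43) higher and Il33 at 4.25-fold lower. The STAT3 and acute phase list had 1 of 18 higher and 3 lower, with Cp at 3.29-fold and Cebpd at 2.18-fold lower, and its median was 0.10, against -0.08 at 8 h. Sterol synthesis genes had 3 of 17 lower (median -0.40), with Insig1 at 3.46-fold (3.09 to 3.88). The macrophage markers Adgre1 and Csf1r were 6.55-fold (3.54 to 13.2) and 3.40-fold (1.57 to 8.14) higher, at 2.78 and 1.08 CPM, beside the higher Mmp12 and Cd36. Mitochondrially encoded transcripts had 1 of 7 lower (median -0.57, percentile 0.01) and nuclear and degradation-sensitive RNAs 1 of 6 lower (median -0.30, percentile 2). The airway list had 2 of 3 higher (median 1.28), Krt8 at 2.47-fold and Krt18 at 2.43-fold, and the fibroblast list had 2 of 7 higher, Npnt and Gsn, and 2 lower, Dcn and Col3a1. Of the endothelial lists, the pan-endothelial one had 3 of 10 higher (median 0.27, percentile 93.5), Flt1 at 2.41-fold, Acvrl1 at 2.19-fold and Ramp2 at 2.04-fold. The aerocyte list had 3 of 7 higher, the venous list 3 of 8 higher, the arterial list 2 higher and 1 lower of 7, the lymphatic list 1 of 2 lower and the general capillary list 0 of 6 called. The 971 calls became 332 with a minimum of 10 CPM (206 higher, 126 lower), 178 with a fold threshold of 4 (57 higher, 121 lower) and 1484 with no filter beyond 1 read (701 higher, 783 lower), so the even split depended on the rule.

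The latest label was addressed by setting the library labelled 20 h against that labelled no LPS, and these columns differed little. At 20 h 65 genes were higher and 12 lower, and none of the genes named in advance was called. S1pr1 was at 1.05 CPM against 0.955 CPM, with an interval of the fold of 0.626 to 1.92. Egr1 was at 1.04-fold (0.869 to 1.24), Stat3 at 1.01-fold (0.944 to 1.09), Sphk1 at 1.36-fold (0.896 to 2.08) and Klf2 at 1.88-fold (1.51 to 2.36), while Spns2 was 1.71-fold below (0.963 to 3.13). Only called genes with at least 100 reads in the higher library were ranked by ratio. Among these, the higher ones with the largest ratios were Ccdc85b at 7.53-fold (6.12 to 9.34), Scand1 at 6.78-fold (4.97 to 9.41), Ier5l at 4.45-fold, Zfp771 at 4.13-fold, the AP-1 gene Jund at 3.16-fold (2.96 to 3.38), Cebpd at 3.13-fold (2.72 to 3.61), Hnrnpa0 at 3.05-fold and the ribosomal protein gene Rpl27 at 2.89-fold. The 12 lower genes had at most 44 reads in the higher library, too few for the rule by which genes were named.

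In the STAT3 and acute phase list 3 of 18 were higher at 20 h and 15 not called (median 0.03): Cebpd, Socs1 at 2.36-fold (1.81 to 3.10) and Cebpb at 2.33-fold (2.11 to 2.58). Jund was the 1 of 26 immediate-early genes called, and the list's median of 0.11 stood at percentile 99.99 of matched random lists; Junb was at 1.99-fold (1.82 to 2.17) and Jun at 1.62-fold, neither called. No G2/M gene of 30 (median -0.02, percentile 28.5), no G1/S gene of 25 (median -0.05, percentile 1.31) and no angiogenesis gene of 23 (median 0.12, percentile 99.8) was called. Mitochondrially encoded transcripts had 0 of 7 called (median 0.09, percentile 99.1), ribosomal proteins 1 of 78 higher (median 0.02, percentile 98.9), the macrophage list 1 of 8 higher (median 0.25, percentile 98.2) and nuclear and degradation-sensitive RNAs 1 of 6 higher (median -0.07, percentile 5.28). Single markers of other cells were higher at low levels: Ear2 at 2.45-fold (1.43 to 4.36), Mmp9 at 2.59-fold (1.33 to 5.36) and the leukocyte gene Cd53 at 2.48-fold, all below 2 CPM. The genes called higher had a median transcript GC content of 57.6% and a median length of 1526 bases, against 49.6% and 3384 over all measured genes. Jund, Junb and Jun had 67.2%, 62.6% and 55.5% GC, and Cebpb, Socs1 and Cebpd 67.2%, 58.8% and 51.6%. The random lists were not matched on GC content, so the percentiles here cannot separate a gene group from a GC trend between these columns. Of the 77 calls, 22 had at least 10 CPM, 9 passed a fold threshold of 4 and 40 the stricter interval, all of them higher genes, and 216 were made with no filter beyond 1 read, 150 higher and 66 lower.

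**Figure D3:**
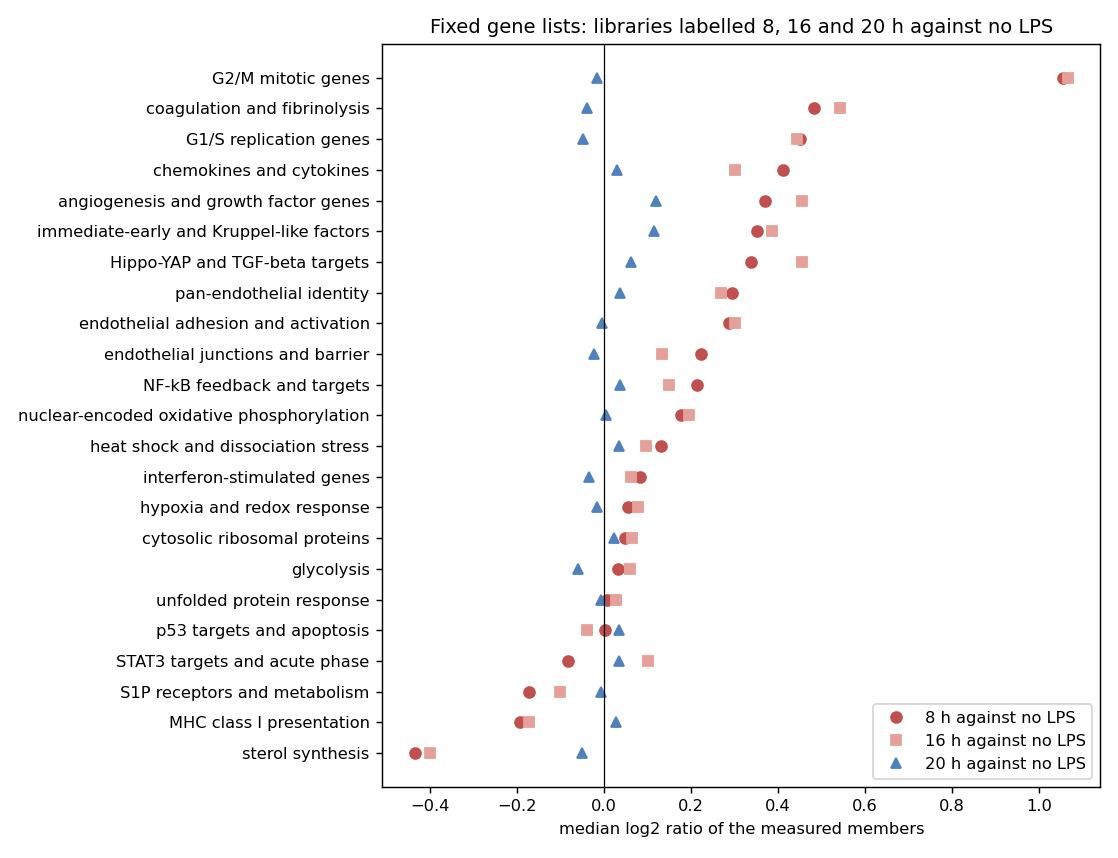
Median log2 ratio of the measured members of each gene list with at least 10 measured genes (x axis), for the libraries labelled 8 h (circles), 16 h (squares) and 20 h (triangles) against that labelled no LPS. G2/M mitotic genes stand at 1.06, 1.07 and -0.02 and sterol synthesis genes at -0.43, -0.40 and -0.05.

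Successive times were compared to place the differences between the labels. Between 8 h and 16 h 19 genes were higher and 9 lower at 16 h, where simulated counts with counting error alone gave 10 false calls. Only Mmp12, 11.7-fold higher (6.46 to 23.1), and Cd36, 4.75-fold higher (3.03 to 7.73), had the 100 reads needed to be named by size. Among macrophage markers Adgre1 was 2.57-fold (1.68 to 4.04) and Csf1r 2.07-fold (1.08 to 4.14) higher at 16 h, the neutrophil list had Mmp9 2.20-fold higher (1.18 to 4.27), and the macrophage list had a median of 0.21 with 2 of 8 members higher. S1pr1, Sphk1, Spns2, Egr1, Klf2 and Stat3 were not called, with S1pr1 at 1.06-fold lower (0.775 to 1.46). The count of 28 became 0 with a minimum of 10 CPM, 2 with a fold threshold of 4 and 4 with the stricter interval, all of them higher, and 172 with no filter beyond 1 read, 92 higher and 80 lower.

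From 16 h to 20 h 546 genes were higher and 454 lower. Spns2 was 12.5-fold lower at 20 h (7.92 to 20.8), Egr1 6.38-fold (5.60 to 7.30), Sphk1 3.19-fold (2.35 to 4.39) and S1pr1 2.72-fold (1.76 to 4.32), and Klf2 and Stat3 were not called. Ikzf2 was 9.09-fold, Adgrg1 7.81-fold and Tinagl1 6.11-fold lower. On the higher side L3mbtl1 was at 26.8-fold (10.2 to 100), Platr26 at 25.7-fold (13.3 to 56.9), Tspoap1 at 17.9-fold (16.1 to 20.0), Nlrp12 at 12.4-fold and Aqp9 at 10.6-fold. Mitotic genes were lower in 18 of 30 cases (median -1.09) and G1/S genes in 4 of 25 (median -0.49), with Tk1 at 4.87-fold and Mki67 at 3.03-fold. Coagulation genes had 4 of 16 lower (median -0.51), Hippo-YAP and TGF-beta genes 4 of 20 (median -0.39) and angiogenesis genes 6 of 23 lower and 1 higher (median -0.23). Sterol synthesis genes had 2 of 17 higher (median 0.40), with Insig1 at 3.67-fold. Mitochondrially encoded transcripts had 1 of 7 higher (median 0.66, percentile 100) and nuclear and degradation-sensitive RNAs 2 of 6 higher (median 0.50, percentile 99.84), while the airway list had 2 of 3 lower (median -1.20). In the STAT3 and acute phase list 4 of 18 were higher and 1 lower, with Lcn2 at 9.35-fold (8.66 to 10.1) and Cebpd at 6.83-fold (5.63 to 8.36) higher. Of these 1000 calls 357 had at least 10 CPM, 152 higher and 205 lower, and 184 passed a fold threshold of 4, 134 higher and 50 lower, so the side with more genes depended on the rule.

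Over the 10780 genes with a mean above 50 reads, the libraries labelled 8 h and 16 h had a chi-square of 1.65 per gene against 1 for sampling noise alone, and those labelled no LPS and 20 h had 7.90. The pairs 8 h with no LPS and 20 h with 16 h had 81.7 and 83.1. The value of 1.65 was the smallest of the 6 pairs. Whether any of the columns came from separate animals or preparations was not tested.

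The overlap of the calls against no LPS was counted to describe which genes recurred over the times. Of the genes higher at 8 h and at 16 h, 405 were shared, and of the lower genes 402 were. Independent lists of these sizes would share 20.4 and 19.9. Simulated unchanged libraries set against the same control shared 0.850 higher and 0.650 lower genes with counting error alone, 30.5 and 16.0 with a simulated biological coefficient of variation of 0.2, and 584 and 426 with one of 0.4, at which each comparison made 2862 calls on average. The control was a single library and could not be split, so part of the excess may come from it. The pairs 8 h with no LPS and 20 h with 16 h have no library in common. Of the 494 genes higher at 8 h, 343 were called lower from 16 h to 20 h, and of the 487 lower genes 361 were called higher. For those genes this argues against the control library as the source of the calls. With 20 h, the 8 h calls shared 5 higher and 4 lower genes (2.72 and 0.495 if independent) and the 16 h calls 9 and 4 (2.69 and 0.491), and the simulated values with counting error alone were 0.450 and 0.550, and 0.750 and 0.750. With a simulated biological coefficient of variation of 0.2 they were 30.6 and 17.4 for 8 h with 20 h and 29.7 and 15.6 for 16 h with 20 h. With one of 0.4 they were 577 and 421, and 580 and 420. At 0.2 each simulated comparison made 291 calls on average, against 77 calls at 20 h here. The larger simulated overlap therefore cannot show that the shared calls were fewer than unchanged libraries would give. Called in the same direction at all 3 times were 9 genes, 5 higher and 4 lower, and with a fold threshold of 4 there were 0. Among 633 genes higher at any time, the highest level was at 8 h for 270, at 16 h for 305 and at 20 h for 58. With a fold threshold of 4 the counts were 37, 37 and 7.

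A straight line over the labelled hours was the relation fixed for testing. Of 11803 genes, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.9999. At an unadjusted p of 0.05 there were 42 genes, and DESeq2 gave 0 genes adjusted and 25 unadjusted. The order of the times and log2 of the hour plus 1 in place of the hours gave 0 genes adjusted, and 50 and 38 unadjusted. The fit estimated a biological coefficient of variation of 0.247, and with simulated counts of that spread 8 of 100 genes at 2-fold by the last hour and 73 of 100 at 4-fold passed. That estimate depended on single libraries: it was 0.131 without the library labelled 20 h, 0.180 without no LPS, 0.272 without 8 h and 0.288 without 16 h. The smallest p among positive slopes belonged to Rpl27, with a slope of 0.07 log2 units per hour, followed by Junb, Ccdc85b, Jun and Scarf2. Among negative slopes they belonged to Pabpc1l, at -0.08 log2 units per hour, Myo1a, Rpl18, Rpl37 and Efhb. None of the 46 gene lists had a member that passed, and 0 passed when adjusted over the list alone. The test counted departures from a straight line as spread, so differences that were present at 8 h and 16 h and small at 20 h were not tested by it. Without the library labelled 20 h, 0 genes passed and 2021 had an unadjusted p under 0.05, and without that labelled no LPS 0 passed and 555 did. The unadjusted count fell to 15 without the library labelled 8 h and to 24 without that labelled 16 h.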

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

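Genes called in opposite directions at different labelled times stood out, and 3 genes met this description against the library labelled no LPS. Cebpd, a transcription factor gene of the acute phase response (chromosome 16, 15887286 to 15891031, plus strand), had a log2 ratio of -1.20 at 8 h and 1.64 at 20 h. Nkpd1 had -1.78 at 8 h and 1.11 at 20 h. Yjefn3 had -0.94 at 16 h and 1.11 at 20 h. Cebpd and Nkpd1 were also called lower at 16 h. The difference was not tested for any of them, since each time had 1 library. Cebpd rested on 263, 115, 118 and 806 reads in the libraries labelled no LPS, 8 h, 16 h and 20 h, Nkpd1 on 42, 11, 2 and 91, and Yjefn3 on 39, 22, 19 and 85.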

How the results depend on the processing

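The correction for GC content was chosen after seeing the data, and the other alternatives were planned and all were run. No paired analysis was possible because each label had 1 library. In the order 8 h, 16 h and 20 h against no LPS, 16 h against 8 h and 20 h against 16 h, the counts of called genes were 981, 971, 77, 28 and 1000. A minimum of 10 CPM gave 332, 332, 22, 0 and 357, and a fold threshold of 4 gave 187, 178, 9, 2 and 184, both by their construction as stricter rules. In the same order without 16 h against 8 h, higher and lower genes were 207 and 125, 206 and 126, 22 and 0, and 152 and 205 at 10 CPM, and 61 and 126, 57 and 121, 9 and 0, and 134 and 50 at a fold of 4, so the balance of directions depended on the rule. With no filter beyond 1 read 16 h against no LPS gave 1484, 20 h against no LPS 216 and 16 h against 8 h 172, since more genes entered. The stricter interval gave 40 for 20 h against no LPS and 4 for 16 h against 8 h. The 3 other scalings, thinning and the removal of marker genes moved no count by over 1.5 times, and after GC correction the counts were 1009, 997, 75, 41 and 1021. With a fold threshold of 4 the genes called at all 3 times numbered 0 and those highest at 8 h 37 of 81. Of 4112 recomputed values of single genes and lists, 4090 stayed within their bound, 22 moved beyond it (all single genes) and 0 reversed. The bound was the counting interval for genes. For list medians it was set by the spread of the members or by a small fixed shift, so the 2 kinds are not judged alike. The trend test gave 0 genes under every alternative and with each library left out, with the smallest adjusted p, 0.0900, in DESeq2. Depth limits the folds of genes below about 1 CPM, S1pr1 among them.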

Other observations

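Tests of shallow sequencing, of loss after LPS, of mesenchymal cells, of the ratio of totals, of repeat preparations, of the mean GC trend and of recovery above 65% GC were chosen after the results were seen, as were the gene lists and single genes of the next paragraph and the limit of the conclusion on other lung cells to the listed types with no gene at 10 CPM. The other tests were set out before their results were seen.

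Mesenchymal genes and genes of amino acid supply were well expressed in these libraries. Of 24 genes of mesenchymal regulators and surface proteins, a list drawn up after seeing the data, 18 reached 10 CPM in the library labelled no LPS, with a median of 51.7 CPM. Twist1 stood at 34.9 CPM, the BMP antagonist gene Grem1 at 229 CPM and the PDGF receptor gene Pdgfra at 34.1 CPM there, while Thy1 and the pericyte gene Pdgfrb had 0 and 23 reads. All 30 measured genes of amino acid synthesis and tRNA charging reached 10 CPM, with a median of 466 CPM, among them Asns at 712 CPM, Psat1 at 619 CPM and Shmt2 at 721 CPM. The endoplasmic reticulum chaperone gene Hspa5 was the most abundant in the library labelled no LPS, at 7879 CPM. The cell cycle inhibitor gene Cdkn2a had 0, 0, 0 and 1 reads in the libraries labelled no LPS, 8 h, 16 h and 20 h. The amino acid list had 0 members higher and 2 lower at 8 h, Aldh1l2 and Atf5 among its 30, and its median stood at percentile 51.9.

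The near absence of endothelial transcripts was weighed first. Shallow sequencing is argued against by the smallest total of 27566454 reads, loss of single genes in counting by the 19 of 28 pan-endothelial genes below 1 CPM, and loss after LPS by the list's median of 0.212 CPM in the library labelled no LPS. The medians of the 14 lists of other lung cells with no LPS all lay below the bound of 10 CPM. The highest was 0.991 CPM, for leukocytes. This argues against neutrophils, T cells, B cells, NK cells, platelets, erythroid cells and smooth muscle as the content of the sort. No counted gene of their lists reached 10 CPM in any library. For the other lists the median cannot decide, since some of their genes reached 10 CPM in at least 1 library. They were 5 of 16 fibroblast, 3 of 20 macrophage, 2 of 12 alveolar type 2, 2 of 14 airway, 1 of 12 leukocyte, 1 of 10 alveolar type 1 and 1 of 8 mesothelial genes. The fibroblast list median was 0.0885 CPM with no LPS. Other mesenchymal cells also stay open, with a median of 51.7 CPM on a list drawn up after seeing the data. By the labels, the CD45 gate would remove leukocytes and the CD31 gate fibroblasts and other mesenchymal cells. Whether these columns came through the gates is itself open, since Pecam1 had 7, 2, 2 and 1 reads with no LPS and at 8, 16 and 20 h. The gates therefore cannot count against any of these cells. The columns may hold RNA of cells other than those the labels name. The highest median of the 6 endothelial lists in any library was 1.62 CPM, below the bound of 10 CPM set for sorted endothelium. That value restates the near absence of endothelial transcripts and is no separate support for this explanation. Which cells, and whether the table or the labels are at fault, was not tested.

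The resemblance of the libraries labelled no LPS and 20 h, and of those labelled 8 h and 16 h, was weighed next. Depth is argued against by a ratio of 1.05 between the largest and the smallest total, at which the planned thinning to equal totals (988 genes called between 8 h and no LPS) could not decide. An endotoxin response that had ended by 20 h stays open: 2 of 5 inflammatory lists lay above the percentile bound at 8 h, fewer than such a response would need and more than would exclude it. Repeat preparations of a pair of conditions under 4 time labels also stay open. Within the pairs 105 genes were called, 77 between no LPS and 20 h and 28 between 8 h and 16 h. They were 10.7% of the number between 8 h and no LPS, against a bound of 10%, and simulated counting error alone gave 22 false calls there. A course that returned by 20 h would also give a low count, so the count cannot decide. With 1 library per label, repeat preparations and such a course cannot be told apart.

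The genes that separated 20 h from no LPS were weighed last. A correction for GC content left 84.4% of the 77 calls, between the bounds set for and against a GC bias, so that bias stays open in part. For genes of up to 65% GC, the mean GC trend as the whole cause is argued against by its size, 0.293 log2 units at 65% GC. The smoothed trend cannot decide for genes above 65% GC, since only 38 measured genes lay there. The median log2 ratio of the genes called higher was 1.22. That median was 1.09 after the correction, which adds nothing, since these genes were picked for a fold of at least 2. Of 38 measured genes with over 65% GC, 16 were called higher, Jund, Scand1 and Zfp771 among them at 67.2%, 68.4% and 68.7%. From 16 h to 20 h 14 of the 38 were called higher, against 5 at 8 h and 5 at 16 h over no LPS. The library labelled 20 h thus stood apart in these genes, and better recovery of such transcripts in it may account for them. Calls from 16 h to 20 h may carry the same effect. A response to LPS at 20 h stays open and was not tested.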
